A study of Arabidopsis thaliana with 12 samples.

How the data were processed

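The samples are Arabidopsis thaliana Col-0 seedlings grown in 96-well plates at 22 °C and treated for 6 h in liquid medium under continuous light with DMSO or with 10 µM ABA, 3'-propyl ABA or 3'-butyl ABA. The sample labels give the age as 8 days and the series text as 7 days. Strand-specific poly(A) libraries were sequenced in pairs on an Illumina HiSeq, 3 libraries per treatment and 12 in all. Nothing in the labels says whether the replicates came from separate cultures, and the replicate numbers were not used to pair the samples.

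The deposited files hold 1 column per library and 27655 genes. Their values are TPM made by the authors: each library sums to 1000000 and 99.0% of 3223 low genes had values that were whole multiples of 1 step, within 0.01 of a step. The submitters' processing notes name bcl2fastq and the TAIR10 genome; the aligner, the counting tool and the annotation release are not given in the sources used here. The comparisons had been planned for read counts, with a test on log2 values if the files held normalized values, and the latter was used. From the steps, 1 read in a gene of 1 kb was worth 0.130 to 0.169 TPM and the libraries held an estimated 9.64 to 12.4 times 1000000 reads in genes; this is an estimate that covers counting error only. Gene symbols and coordinates are those of the TAIR10.1 annotation, in which 27445 gene IDs have an entry and 210 do not, 122 of them mitochondrial. Values per gene cannot separate near-identical copies such as LTP3 and LTP4, KIN1 and KIN2, COR15A and COR15B, the LHCB1 and RBCS genes, SAUR19 and SAUR20, the UGT71B genes, AOC1 and AOC2, and VSP1 and VSP2. Pearson correlations of log2 values between replicates were 0.988 to 0.996.

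Values were transformed as log2(TPM + 1), and genes with a mean of at least 1 TPM over the 12 libraries were kept, 19528 in all. One model with a mean per treatment was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust), with 8 residual and a median of 4.05 prior degrees of freedom. The 6 pairwise comparisons of the 4 treatments were tested two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A gene called with an absolute log2 fold change of at least 1 is described as changed at least 2-fold. The test was also run on data simulated at the depths of these libraries, with the same fixed dispersion for every gene. With 67, 66 and 65 genes changed by 0.5, 1 and 2 log2 units in 1 group, it recovered 14.9%, 90.9% and 98.5% of them. Of 145 calls 11 (7.6%) were false, and a comparison without changes gave 0 calls. Neither the dispersion nor the number of changed genes was taken from these libraries, so these shares are not the power of the comparisons here.

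The comparisons, their alternatives, 27 gene lists with 334 genes (305 tested) and the rule for named genes were fixed before the data were examined. The lists cover ABA receptors, PP2C phosphatases, SnRK2 kinases, transcription factors, LEA and dehydration proteins, ABA biosynthesis and catabolism, light harvesting, cell wall expansion, cell cycle, auxin, jasmonate, cytokinin response regulators, immunity, suberin, wax, proline and raffinose, flavonoids, seed maturation, heat shock, clock, nitrate, iron, ribosome biogenesis, and markers of guard cells, root hairs and endodermis. Each list was tested against the other genes with camera at a preset correlation of 0.01, with adjustment over the lists of a comparison. With the correlation estimated from the residuals, 0 of the 81 list calls held. Named genes are the 5 with the largest increase and the 5 with the largest decrease per comparison among called genes whose libraries do not overlap, up to 4 members per list by absolute fold change, all members of the receptor, PP2C and catabolism lists, and up to 5 genes per pair of compounds called in opposite directions. A gene named in 1 comparison may be given in others.

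Single values per library were compared with two-sided exact permutation tests of 3 against 3 libraries. Overlaps were set beside those of independent lists and beside 50 simulated draws without changed genes. In these draws all 12 libraries, DMSO included, were drawn around the DMSO mean of each gene, with genes independent of each other. Alternatives planned for the counts of called genes were quantile normalization, no filter on low genes, only the 6 libraries compared, a replicate block, a threshold of 1 on the absolute log2 fold change, a pseudocount of 0.1, and leaving out each library in turn. Those planned for lists were an estimated correlation and the block, for overlaps the fold change threshold, and for the 29-gene mean the pseudocount and another scaling, run as median-of-ratios scaling in place of TMM. Chosen after the data were seen were median-of-ratios scaling for the other results, quantile normalization for lists, overlaps and the 29-gene mean, every other alternative for overlaps, leaving out each library in turn for the 29-gene mean, leaving out both DMSO replicate 1 and ABA replicate 3, the root marker mean (15 root hair and endodermis genes) as a covariate, the response sizes over genes chosen with another compound, also with that covariate, the fold changes and errors of the genes called between 3'-butyl ABA and ABA with that covariate, the touch and wound genes outside a pattern, and the families and lists of the last part. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No library was left out of the comparisons.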

Results

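The series addresses how the transcripts of Arabidopsis seedlings respond to abscisic acid (ABA), the plant hormone of drought and seed responses, and to a pair of derivatives that carry a propyl or a butyl chain at the 3' position. Each compound was given at 10 µM for 6 h and set against the DMSO vehicle, with 3 libraries per treatment and 12 in all. The deposited values are TPM, and 19528 genes with a mean of at least 1 TPM were tested. Fold changes are differences of means on the log2(TPM + 1) scale, which understates the fold of genes near 0.

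The first principal component, which held 67.1% of the variance, separated DMSO, 3'-propyl ABA, and ABA together with 3'-butyl ABA. DMSO libraries lay between -90.92 and -82.29 on it, ABA libraries between 8.61 and 19.76, 3'-butyl ABA libraries between 4.79 and 12.09, and 3'-propyl ABA libraries between 63.38 and 71.63. The second component, with 16.9% of the variance, placed every 3'-butyl ABA library (31.24 to 41.64) above every ABA library (6.46 to 21.01). On the third component, with 5.6%, ABA replicate 3 stood apart at -44.98 and DMSO replicate 1 was highest at 19.31. The mean log2(TPM + 1) of 15 root hair and endodermis genes was 3.73 in DMSO replicate 1 against 2.63 and 2.58 in the other DMSO libraries, and 3.43, 2.57 and 2.2 in ABA replicates 1 to 3. In the 3'-butyl ABA libraries it was 3.78, 3.26 and 3.75, and in the 3'-propyl ABA libraries 2.69, 2.63 and 2.54.

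**Figure D1:**
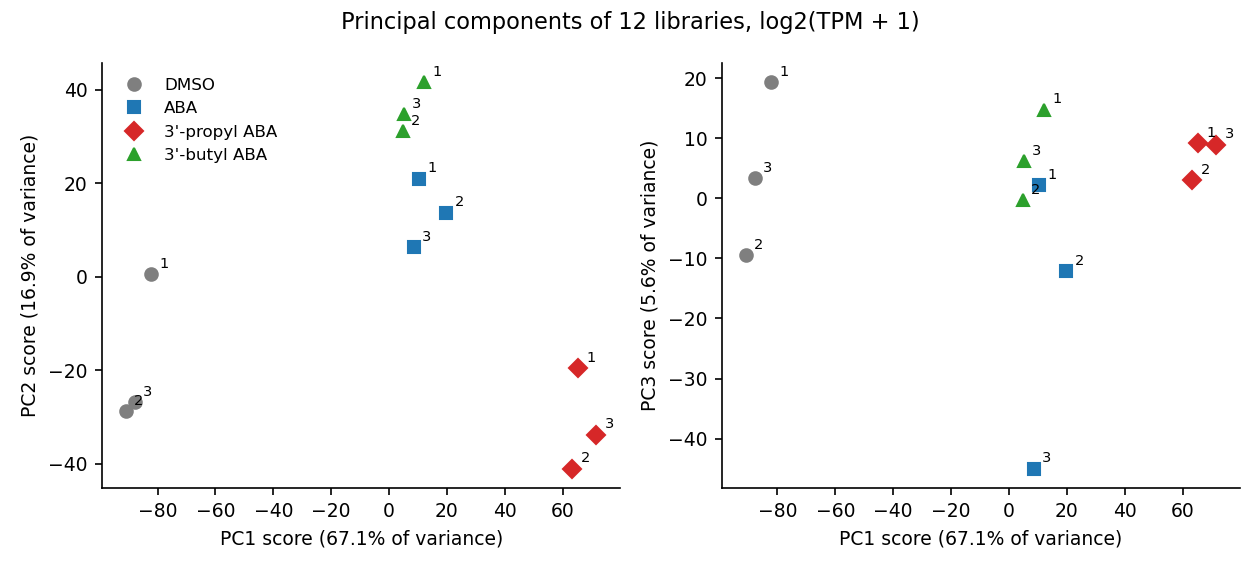
Principal component scores of the 12 libraries on log2(TPM + 1), with the first component (67.1% of the variance) on both horizontal axes and the second (16.9%) or the third (5.6%) on the vertical axes; points are libraries, marked by treatment and numbered by replicate. ABA and 3'-butyl ABA libraries share the range 4.79 to 19.76 on the first component, while 3'-propyl ABA libraries lie between 63.38 and 71.63.

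Within 6 h, ABA raised the genes of dehydration protection and of its own signalling brake, and lowered ABA receptor genes and genes of ribosome assembly. The largest increase was in LTP4, a lipid transfer protein gene (chromosome 5, 23924990 to 23925957 in TAIR10.1), which went from 0.770 ± 0.318 TPM in DMSO to 785 ± 87.2 TPM with ABA (SD, n = 3), a log2 fold change of 8.80 with a standard error of 0.14. KIN1 (8.75 ± 0.36, SE), LTP3 (8.02 ± 0.29), LEA7 (7.46 ± 0.33) and LEA4-5 (7.23 ± 0.13) followed; reads of the close copies LTP3 and LTP4, and KIN1 and KIN2, cannot be separated with certainty in values per gene. The largest decreases were in the cysteine proteinase genes AT1G29090 (-5.96, 79.7 ± 34.6 to 0.211 ± 0.183 TPM) and CP1 (-4.81), in the lipid transfer protein gene EARLI1 (-5.49) and in AT1G27020 (-4.74). AT5G46960, a gene of the invertase/pectin methylesterase inhibitor superfamily, was at 26.3 ± 16.0 TPM in DMSO and listed at 0 in every ABA library.

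Genes of the ABA pathway moved as groups. All 20 tested genes of the list of LEA and dehydration proteins rose with ABA, with a median log2 fold change of 5.48 (camera adjusted p = 1.4e-22, adjusted p = 0.078 with an estimated correlation). RAB18, a dehydrin gene, rose from 13.6 to 863 TPM (5.88 ± 0.09), and RD20, a caleosin gene, rose by 5.38 ± 0.14. All 9 clade A PP2C phosphatase genes, the negative regulators of ABA signalling, rose (median 3, adjusted p = 5.3e-11, adjusted p = 0.092 with an estimated correlation), from HAI1 at 6.09 ± 0.16 and HAI2 at 5.52 ± 0.11 to ABI1 at 2.36 ± 0.10 and HAB2 at 1.16 ± 0.09. Of 9 tested ABA receptor genes, 7 fell, PYL7 rose (0.63 ± 0.17) and PYL9 was not called (median -1.18, adjusted p = 0.0013, adjusted p = 0.27 with an estimated correlation). The receptor genes with the largest decreases were PYL6 (-3.99 ± 0.22), PYL5 (-2.71 ± 0.22), PYL4 (-2.63 ± 0.15) and PYR1 (-2.46 ± 0.18). Among 18 ABA-related transcription factor genes 17 rose and NAC055 was not called (median 2.89, adjusted p = 9.4e-14, adjusted p = 0.092 with an estimated correlation; 18 rose adjusted over the list alone). HB7 was at 5.10 ± 0.16 and AFP1 at 4.59 ± 0.12. Of 10 SnRK2 kinase genes 7 rose and 3 were not called (8 and 2 adjusted over the list alone), with OST1, a kinase of stomatal closure, at 1.51 ± 0.20 (median 0.47, adjusted p = 0.0031, adjusted p = 0.27 with an estimated correlation).

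Both the making and the breakdown of ABA were among the groups that rose. The biosynthesis gene NCED3 rose by 2.62 ± 0.21, and 4 of 5 biosynthesis genes rose in all (median 0.75, adjusted p = 0.0049, adjusted p = 0.092 with an estimated correlation). The ABA 8'-hydroxylase genes CYP707A1 (3.61 ± 0.19), CYP707A2 (1.11 ± 0.13), CYP707A3 (1.34 ± 0.11) and CYP707A4 (1.48 ± 0.15), whose products inactivate ABA, rose, as did the glucosyltransferase gene UGT71B7 (AT3G21790, 0.43 ± 0.08), while UGT71C5 fell by 0.66 and UGT71B6 was not called (list median 1.11, adjusted p = 0.0049, adjusted p = 0.22 with an estimated correlation). In the suberin list, the waxy root barrier, 12 of 13 genes rose and KCS20 fell (median 3.19, adjusted p = 1.1e-07, adjusted p = 0.24 with an estimated correlation). The transporter gene ABCG6 was at 5.11 ± 0.36 and KCS2 at 4.53 ± 0.20. Of 8 cuticular wax genes 5 rose, KCS12 fell and 2 were not called (median 0.91, adjusted p = 0.018, adjusted p = 0.28 with an estimated correlation). CER1 was at 3.58 ± 0.14. In the flavonoid and anthocyanin list 8 of 11 genes rose and 3 were not called (median 1.43, adjusted p = 0.0031, adjusted p = 0.27 with an estimated correlation), with the regulator PAP1 at 2.78 ± 0.24.

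Of the lists that were lower with ABA, ribosome biogenesis had the smallest adjusted p. All 14 ribosome biogenesis genes fell (median -0.89, adjusted p = 1.5e-10, adjusted p = 0.13 with an estimated correlation). The fibrillarin gene FIB2 was at -1.39 ± 0.10 and NOP56 at -1.08 ± 0.08. Of 18 cell wall expansion genes 10 fell, 2 rose and 6 were not called (median -0.31, adjusted p = 0.017, adjusted p = 0.25 with an estimated correlation). The expansin gene EXPA1 was at -2.65 ± 0.18 and EXPA8 at -2.12 ± 0.17. Of 8 type-A cytokinin response regulator genes 4 fell, 1 rose and 3 were not called (median -0.81, adjusted p = 0.017, adjusted p = 0.22 with an estimated correlation). ARR7 was at -2.58 ± 0.26 and ARR6 at -2.34 ± 0.14. Of 11 immunity and salicylic acid genes 8 fell, 1 rose and 2 were not called (median -0.72, adjusted p = 0.021, adjusted p = 0.22 with an estimated correlation). PR5 was at -1.68 ± 0.24 and WRKY33 at -0.95 ± 0.19. The clock list had 6 genes that rose and 6 not called (7 and 5 adjusted over the list alone), with a median of 0.19 (adjusted p = 0.017, adjusted p = 0.22 with an estimated correlation), PRR9 at 1.31 ± 0.15 and ELF4 at 0.90 ± 0.13.

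The other lists were not called as sets with ABA against DMSO. Of 20 light harvesting and Rubisco genes 11 rose, 3 fell and 6 were not called (adjusted p = 0.051), and 5 rose with quantile normalization; RBCS1B fell by 1.41. Jasmonate genes gave 8 up and 2 down of 20 (adjusted p = 0.15). The storage protein gene VSP2 was at 3.94 ± 0.29. Proline and raffinose genes gave 5 up and 2 down of 10 (adjusted p = 0.051; called with quantile normalization, 0.038), with P5CS1, which makes proline, at 4.18 ± 0.11. Auxin genes gave 2 up and 6 down of 16 (adjusted p = 0.24), cell cycle genes 3 down of 19 (adjusted p = 0.34), guard cell and stomatal lineage markers 5 down of 12 (adjusted p = 0.057), iron deficiency genes 2 down of 3 (adjusted p = 0.23) and nitrate genes 1 down of 4 (adjusted p = 0.51). Seed maturation genes gave 2 up of 6, the oil body genes OLEO1 and OLEO2 (adjusted p = 0.051; called with quantile normalization, 0.038); the mean log2(TPM + 1) of this list was 3.33, 4.16 and 5.22 in the 3 ABA libraries. None of 7 heat shock genes or 7 root hair markers was called (adjusted p = 0.34 and 0.43), and 1 of 8 endodermis markers, CASP5, rose (adjusted p = 0.93). Except where given, counts adjusted over the list alone equalled those over all genes.

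In total, 4295 genes rose and 4821 fell with ABA, 46.7% of those tested, and 1326 and 712 of them by at least 2-fold. The majority direction is not stable. With median-of-ratios scaling 4616 rose and 4511 fell, without DMSO replicate 1 4509 and 4430, and with quantile normalization 4147 and 5266. The 3 libraries of each treatment did not overlap for 53.1% of the genes, where chance gives 10% on average. The 95% interval of a log2 fold change reached a median of 0.261 to either side.

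3'-propyl ABA raised the LEA, PP2C, transcription factor, biosynthesis and catabolism lists of the ABA pathway, and lowered light harvesting, cell cycle and auxin genes as sets. None of these set calls holds with an estimated correlation (adjusted p of at least 0.16). LTP4 reached 3463 ± 511 TPM (log2 fold change against DMSO 10.94 ± 0.14, SE, n = 3), KIN1 5206 ± 291 TPM (9.94 ± 0.36) and LEA4-5 876 ± 93.0 TPM (8.61 ± 0.13). LTP3 (9.49 ± 0.29) and LEA7 (9.08 ± 0.33) were the other leading increases. Among the decreases, AT1G27020 was at -6.00 ± 0.25, the methyltransferase gene AT1G15125 at -5.75 ± 0.39, EARLI1 at -5.65 ± 0.45 and CP1 at -5.56 ± 0.41. AT1G29090, at 79.7 ± 34.6 TPM in DMSO, was listed at 0 in all 3 libraries with 3'-propyl ABA.

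All 20 LEA and dehydration genes rose against DMSO (median 7.08, adjusted p = 4.2e-17, adjusted p = 0.16 with an estimated correlation), as did all 9 PP2C genes (median 3.70, adjusted p = 9.5e-09, adjusted p = 0.16 with an estimated correlation) and all 13 suberin genes (median 3.67, adjusted p = 9.3e-08, adjusted p = 0.28 with an estimated correlation). RAB18 rose by 7.90, RD20 by 7.53, HAI1 by 7.19 and KCS2 by 6.38. Of 18 ABA-related transcription factor genes 17 rose (median 3.67, adjusted p = 1.2e-11, adjusted p = 0.16 with an estimated correlation). HB7 was at 6.10, AFP1 at 5.84 and RD26 at 5.01. Of the receptor genes 7 fell and 2, PYL7 and PYL9, were not called (median -1.92, adjusted p = 0.0028, adjusted p = 0.33 with an estimated correlation). PYL4 went from 252 to 7.32 TPM (-4.93 ± 0.15) and PYL6 from 34.1 to 0.125 TPM (-4.96 ± 0.22). The catabolism list had 5 genes up, UGT71C5 down (-1.31) and UGT71B6 not called (median 2.8, adjusted p = 0.0028, adjusted p = 0.23 with an estimated correlation). CYP707A1 was at 4.54 and CYP707A3 at 3.55. Biosynthesis genes (4 of 5 up, median 1.66, adjusted p = 0.0088, adjusted p = 0.16 with an estimated correlation) and SnRK2 genes (8 up, SNRK2.5 down, median 0.67, adjusted p = 0.008, adjusted p = 0.33 with an estimated correlation) rose too, with SNRK2.7 at 3.95 ± 0.30. Wax genes (6 of 8 up, KCS12 down, median 1.68, adjusted p = 0.004, adjusted p = 0.28 with an estimated correlation) included CER1 at 5.07 and KCS6 at 1.85. Flavonoid and anthocyanin genes (10 of 11 up, median 1.69, adjusted p = 0.0023, adjusted p = 0.28 with an estimated correlation) included PAP1 at 4.79 and PAP2 (MYB90) at 3.76.

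Of 20 light harvesting and Rubisco genes 14 fell with 3'-propyl ABA, 0 rose and 6 were not called (median -0.54, adjusted p = 0.01, adjusted p = 0.6 with an estimated correlation). RBCS1B fell by 3.27 ± 0.19, RBCS2B by 1.75 ± 0.10 and LHCB5 by 0.75 ± 0.12. Ribosome biogenesis genes all fell, 14 of 14 (median -1.42, adjusted p = 9.1e-08, adjusted p = 0.23 with an estimated correlation). FIB2 was at -2.12 and NOP56 at -1.71. Of 19 cell cycle and DNA replication genes 13 fell (median -0.59, adjusted p = 0.0083, adjusted p = 0.46 with an estimated correlation). CYCD3;3 was at -1.1 and PCNA2 at -0.95; 10 genes of the list fell with median-of-ratios scaling and 9 with quantile normalization. Cell wall expansion genes gave 11 down and 1 up of 18 (13 and 2 adjusted over the list alone; median -0.99, adjusted p = 0.013, adjusted p = 0.28 with an estimated correlation). EXPA8 was at -5.11 ± 0.17, EXPA1 at -4.12 ± 0.18 and XTH20 at -2.63 ± 0.23. Auxin genes gave 12 down and 2 up of 16 (median -0.89, adjusted p = 0.013, adjusted p = 0.28 with an estimated correlation), with IAA29, an auxin response repressor gene, at -3 ± 0.21, and type-A response regulators 5 down and 1 up of 8 (median -1.45, adjusted p = 0.043, adjusted p = 0.28 with an estimated correlation). ARR7 was at -4.63 ± 0.26. Jasmonate genes gave 9 up and 3 down of 20 (8 and 3 adjusted over the list alone; median 0.25, adjusted p = 0.043, adjusted p = 0.62 with an estimated correlation); the set call is lost with median-of-ratios scaling (0.071) and with quantile normalization (0.059). Immunity genes went both ways, 3 up and 6 down of 11 (4 and 7 adjusted over the list alone; adjusted p = 0.49). FLS2, a receptor of bacterial flagellin, fell by 2.41 ± 0.13, and WRKY33 (1.45 ± 0.19), WRKY53 (0.98 ± 0.26) and WRKY70 (1.81 ± 0.33), transcription factor genes of defence, rose. Guard cell and stomatal lineage markers gave 9 down and 2 up of 12 (10 and 2 adjusted over the list alone; adjusted p = 0.069; called with median-of-ratios scaling, 0.041). MYB60 was at -2.22 ± 0.13. The nitrate reductase gene NIA1 fell by 1.36 ± 0.06.

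With 3'-propyl ABA 5371 genes rose and 7518 fell, 66.0% of those tested, 2213 and 2520 of them by at least 2-fold. The libraries did not overlap for 69.0% of the genes. Median-of-ratios scaling moved the median log2 fold change of all genes from -0.116 to 0.005, and with it 6530 genes rose and 6363 fell.

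3'-butyl ABA moved the LEA, PP2C and transcription factor lists by medians near those of ABA, and raised light harvesting genes. KIN1 rose by 8.17 ± 0.36 against DMSO (SE, n = 3), to 1528 ± 160 TPM (SD), LTP4 by 8.00 ± 0.14 to 447 ± 28 TPM, and the lipid transfer protein gene AT2G37870 by 7.45 ± 0.37 to 556 ± 50.4 TPM. LEA7 rose by 7.27 ± 0.33 and LTP3 by 6.85 ± 0.29. CP1 fell by 4.68 ± 0.41 and the helix-loop-helix factor gene AT2G43140 by 3.78 ± 0.22. AT1G29090, AT5G46960 and AT5G01881, at 79.7 ± 34.6, 26.3 ± 16.0 and 16.2 ± 3.97 TPM in DMSO, were listed at 0 in all 3 libraries with 3'-butyl ABA.

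All 20 LEA and dehydration genes rose (median 5, adjusted p = 1.5e-19, adjusted p = 0.11 with an estimated correlation), as did all 9 PP2C genes (median 3.17, adjusted p = 3e-10, adjusted p = 0.11 with an estimated correlation). Of 18 ABA-related transcription factor genes 17 rose (18 adjusted over the list alone; median 2.96, adjusted p = 7.9e-13, adjusted p = 0.11 with an estimated correlation), and 12 of 13 suberin genes rose with 1 down (median 3.24, adjusted p = 8.9e-07, adjusted p = 0.33 with an estimated correlation). HAI1 was at 6.24, HB7 at 5.14, RAB18 at 5.28 and ABCG6 at 5.10. Receptor genes gave 6 down and 2 up, PYL7 (1.31) and PYL9 (0.79), of 9 (median -1.27, adjusted p = 0.011, adjusted p = 0.39 with an estimated correlation). PYL6 was at -2.48 ± 0.22 and PYL4 at -2.12 ± 0.15. Biosynthesis (4 of 5 up, adjusted p = 0.0074, adjusted p = 0.11 with an estimated correlation), catabolism (5 of 7 up; 5 up and 1 down adjusted over the list alone; adjusted p = 0.0074, adjusted p = 0.27 with an estimated correlation) and SnRK2 genes (7 of 10 up, adjusted p = 0.0038, adjusted p = 0.35 with an estimated correlation) had NCED3 at 3.63 ± 0.21, CYP707A1 at 3.71 ± 0.19 and OST1 at 1.70 ± 0.20. In the flavonoid list 6 of 11 rose (adjusted p = 0.02, adjusted p = 0.39 with an estimated correlation). F3H was at 2.13.

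Of 20 light harvesting and Rubisco genes 16 rose with 3'-butyl ABA, 3 fell and 1 was not called (median 0.56, adjusted p = 0.002, adjusted p = 0.5 with an estimated correlation; 11 rose and 4 fell with quantile normalization). LHCB2.3 went from 100.7 ± 16.1 to 355.1 ± 18.1 TPM (1.82 ± 0.27) and LHCB2.1 rose by 1.25 ± 0.13, while RBCS1B fell by 0.93 ± 0.19. All 14 ribosome biogenesis genes fell (median -0.99, adjusted p = 1.8e-10, adjusted p = 0.13 with an estimated correlation). FIB2 was at -1.50. Cell wall expansion genes gave 10 down and 4 up of 18 (median -0.42, adjusted p = 0.02, adjusted p = 0.33 with an estimated correlation; the set call is lost with quantile normalization, 0.054). XTH20 was at -2.16 and EXPA1 at -1.64. Guard cell and stomatal lineage markers gave 7 down and 1 up of 12 (median -0.43, adjusted p = 0.034, adjusted p = 0.39 with an estimated correlation). EPF2 was at -1.61 and MYB60 at -1.19. The clock list gave 6 up of 12 (7 adjusted over the list alone; adjusted p = 0.027, adjusted p = 0.27 with an estimated correlation). PRR9 was at 1.86. The galactinol synthase gene GOLS2 rose by 4.77 ± 0.19 and P5CS1 by 4.70 ± 0.11, in a proline and raffinose list with 6 up and 2 down of 10 (adjusted p = 0.055; called with quantile normalization, 0.033). Some lists called with ABA were not called with 3'-butyl ABA against DMSO. These were wax genes (5 up and 1 down of 8; 5 and 2 adjusted over the list alone; median 0.55, adjusted p = 0.11), type-A response regulators (4 down of 8, median -0.65, adjusted p = 0.073) and immunity genes (5 down of 11, median -0.36, adjusted p = 0.076). Nor were cell cycle (adjusted p = 0.39), auxin (0.33), jasmonate (0.86), seed maturation (0.11), heat shock (0.64), nitrate (0.11), iron (0.33), root hair (0.46) or endodermis genes (0.11). Set directly against ABA, type-A response regulators and immunity genes were not called with camera (adjusted p = 0.64 and 0.26). Wax genes were called lower there (adjusted p = 0.00021, adjusted p = 0.46 with an estimated correlation). In total 4899 genes rose and 4991 fell against DMSO, 50.6% of those tested, 1544 and 681 of them by at least 2-fold, and the libraries did not overlap for 60.6% of the genes. The balance of directions depends on scaling. With quantile normalization 4465 rose and 5961 fell, and with median-of-ratios scaling 5046 and 4894.

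**Figure D2:**
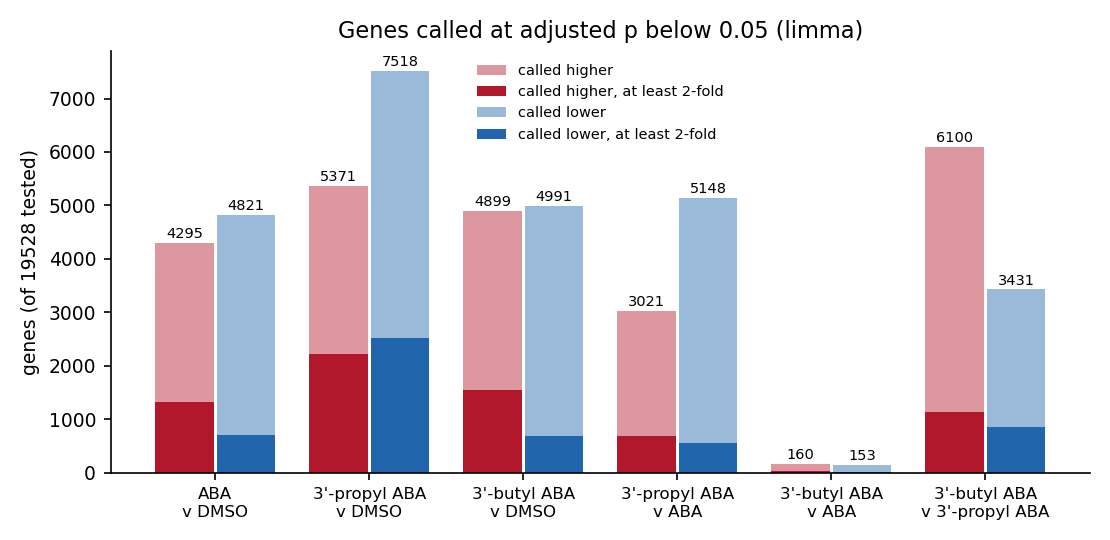
Number of genes called at each comparison with limma, of 19528 tested, for genes called higher and lower; the dark part of each bar is the genes with an absolute log2 fold change of at least 1. The comparison of 3'-butyl ABA with ABA has 160 genes called higher and 153 lower, and every other comparison has at least 3021 in each direction.

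Set against ABA at the same 10 µM and 6 h, 3'-propyl ABA gave higher levels of dehydration, phosphatase and ABA breakdown genes and lower levels of light harvesting, ribosome biogenesis and cell cycle genes. RD20 went from 214.5 ± 35.5 to 948.6 ± 113 TPM (log2 difference 2.15 ± 0.14, SE, n = 3), RAB18 from 863.4 ± 80.1 to 3512 ± 479 TPM (2.02 ± 0.09) and LTP4 from 785 to 3463 TPM (2.14 ± 0.14). In the LEA and dehydration list 18 of 20 genes were higher and COR15B and KIN2 were not called (median 1.12, adjusted p = 2.4e-11, adjusted p = 0.26 with an estimated correlation). Of 9 PP2C genes 8 were higher and AHG1 was not called (0.48 ± 0.40; list median 1.00, adjusted p = 2.9e-07, adjusted p = 0.26 with an estimated correlation). ABI2 was at 1.45 ± 0.10, HAB1 at 1.2 ± 0.11, HAI1 at 1.1 ± 0.16 and ABI1 at 1.00 ± 0.10. The hydroxylase genes CYP707A3 (17.09 to 82.91 TPM, 2.21 ± 0.11), CYP707A4 (1.92 ± 0.15), CYP707A2 (1.70 ± 0.13) and CYP707A1 (0.93 ± 0.19) were higher, in a catabolism list with 5 up, UGT71C5 down (-0.65) and UGT71B6 not called (median 0.93, adjusted p = 0.00082, adjusted p = 0.26 with an estimated correlation).

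Of 18 ABA-related transcription factor genes 14 were higher (15 adjusted over the list alone; median 0.98, adjusted p = 1.6e-07, adjusted p = 0.26 with an estimated correlation). MYB2 was at 1.89 ± 0.18, NAC019 at 1.69 ± 0.28 and RD26 at 1.41 ± 0.17. Receptor genes were lower in 6 of 9 cases (median -0.77, adjusted p = 0.014, adjusted p = 0.41 with an estimated correlation), PYL4 by -2.31 ± 0.15, PYL6 by -0.96 ± 0.22 and PYL8 (RCAR3) by -0.84 ± 0.10. Among SnRK2 genes SNRK2.7 was higher by 2.54 ± 0.30, and the list (3 up, 1 down, 6 not called) had an adjusted p of 0.16. Biosynthesis genes were not called as a set either (2 of 5 up, median 0.19, adjusted p = 0.12). Suberin (7 of 13 up, median 0.76, adjusted p = 0.00029, adjusted p = 0.41 with an estimated correlation), wax (5 of 8 up, 1 down, median 0.91, adjusted p = 0.0024, adjusted p = 0.33 with an estimated correlation) and flavonoid genes (6 of 11 up, 1 down, median 0.32, adjusted p = 0.013, adjusted p = 0.41 with an estimated correlation) were higher, with KCS2 at 1.85 ± 0.20, CER1 at 1.49 ± 0.14, CER3 at 1.44 ± 0.12, PAP2 at 2.24 ± 0.37 and PAP1 at 2.01 ± 0.24.

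All 20 light harvesting and Rubisco genes were lower with 3'-propyl ABA than with ABA (median -0.80, adjusted p = 3.8e-08, adjusted p = 0.36 with an estimated correlation). RBCS1B was at -1.85 ± 0.19, LHCB2.3 at -1.59 ± 0.27 and LHCB5 at -0.98 ± 0.12. Ribosome biogenesis genes were lower in 13 of 14 cases (14 adjusted over the list alone; median -0.52, adjusted p = 2e-06, adjusted p = 0.33 with an estimated correlation), cell cycle genes in 12 of 19 (14 adjusted over the list alone; median -0.43, adjusted p = 0.00083, adjusted p = 0.41 with an estimated correlation). CYCB1;2 was at -0.84 ± 0.13. Cell wall expansion (10 of 18 down, 1 up; 11 and 2 adjusted over the list alone; median -0.71, adjusted p = 0.026, adjusted p = 0.36 with an estimated correlation) and auxin genes (10 of 16 down, 2 up; 11 and 2 adjusted over the list alone; median -0.66, adjusted p = 0.01, adjusted p = 0.33 with an estimated correlation; 7 down with quantile normalization) were lower too, with EXPA8 at -2.99 ± 0.17, EXPA1 at -1.47 ± 0.18, the auxin transporter gene PIN7 at -1.07 ± 0.09 and IAA29 at -3.76 ± 0.21. WRKY33 (2.4 ± 0.19), WRKY53 (2.07 ± 0.26) and WRKY70 (1.64 ± 0.33) were higher and FLS2 lower (-1.54 ± 0.13), in an immunity list with 3 up, 4 down and a median of -0.14 (0.06 with quantile normalization; adjusted p = 0.64). The jasmonate list (4 up, 2 down; 4 and 0 adjusted over the list alone; median -0.05; 0.05 with median-of-ratios scaling and 0.02 with quantile normalization; adjusted p = 0.21) and the clock list (3 up, 4 down; 3 and 5 adjusted over the list alone; median -0.06; 0.05 with median-of-ratios scaling; adjusted p = 0.89) were not called, nor were root hair (adjusted p = 0.41), endodermis (adjusted p = 0.74), guard cell (adjusted p = 0.3), nitrate (adjusted p = 0.051; called as lower with quantile normalization, 0.044), iron (adjusted p = 0.27), seed maturation (adjusted p = 0.25) or heat shock genes (adjusted p = 0.85).

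The 5 largest increases of 3'-propyl ABA over ABA were in AT5G39520 (3.56 ± 0.21, SE), the LEA domain gene AT2G18340 (3.42 ± 0.18), the calcium-binding protein gene AT4G27280 (3.38 ± 0.28), TCH4, a touch-induced xyloglucan endotransglucosylase gene (3.29 ± 0.26; chromosome 5, 23307006 to 23308680), and the alpha-amylase gene AMY1 (3.23 ± 0.22). After IAA29, the largest decreases were in SAUR20 (-3.55 ± 0.39), SAUR19 (-3.32 ± 0.22) and AT5G63180 (-3.30 ± 0.16); RGF6, a root growth factor gene, was at 9.61 ± 2.7 TPM with ABA and listed at 0 with 3'-propyl ABA. In total 3021 genes were higher and 5148 lower, 41.8% of those tested, with 692 and 557 at least 2-fold apart, and the libraries did not overlap for 51.4% of the genes. The balance of directions depends on scaling: 37.0% of called genes were higher here, 54.0% with median-of-ratios scaling, which moved the median of all genes from -0.097 to 0.004, and 45.2% with quantile normalization.

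3'-butyl ABA, whose chain is 1 carbon longer than that of 3'-propyl ABA, had few genes called against ABA at the matched dose. No PP2C gene was called between them with limma (median difference 0.08; camera adjusted p = 0.45): the 95% interval of the difference was 0.07 to 0.50 for ABI1, -0.19 to 0.24 for ABI2, -0.18 to 0.50 for HAI1, and widest, -0.92 to 0.84, for AHG1. For CYP707A3 it was -0.14 to 0.33, for HB7 -0.32 to 0.40, for FIB2 -0.32 to 0.10 and for OST1 -0.25 to 0.62. Across all 19528 genes the interval lay within 1 log2 unit of 0 for 91.2% and within 0.5 for 63.8%. None of the 10 SnRK2, 18 transcription factor, 7 catabolism, 13 suberin or 14 ribosome biogenesis genes was called either (adjusted p = 0.98, 0.45, 0.92, 0.64 and 0.16); adjusted over the list alone 1 catabolism gene was higher.

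Some sets differed between these compounds, and among the fixed lists the root hair and endodermis markers had the largest medians. LEA and dehydration genes were lower with 3'-butyl ABA (0 up, 3 down, 17 not called; 8 down adjusted over the list alone; median -0.31, adjusted p = 9.9e-07, adjusted p = 0.46 with an estimated correlation). RAB18 was at 567.5 ± 12.4 TPM against 863.4 ± 80.1 TPM with ABA, a difference of -0.60 with a 95% interval of -0.80 to -0.40. ABA receptor genes were higher (1 up, 8 not called; 5 up adjusted over the list alone; median 0.54, adjusted p = 0.00021, adjusted p = 0.62 with an estimated correlation). PYL6 was at 1.51 (1.03 to 1.99). Light harvesting genes were higher (1 up, 19 not called; 6 up adjusted over the list alone; median 0.27, adjusted p = 9.9e-07, adjusted p = 0.65 with an estimated correlation). Wax genes were lower (1 down; 5 down adjusted over the list alone; median -0.38, adjusted p = 0.00021, adjusted p = 0.46 with an estimated correlation). Nitrate genes were lower too (1 down of 4; 3 adjusted over the list alone; adjusted p = 0.0068, adjusted p = 0.46 with an estimated correlation; 0.07 with quantile normalization). NIA1 was at -0.39 (-0.52 to -0.26). Jasmonate genes were lower as a set (0 of 20 called; 1 down adjusted over the list alone; median -0.28, adjusted p = 0.008, adjusted p = 0.85 with an estimated correlation). Proline and raffinose genes were higher (2 of 10 up; 3 adjusted over the list alone; median 0.31, adjusted p = 0.04, adjusted p = 0.65 with an estimated correlation). Root hair markers (0 of 7 called, median 0.89, adjusted p = 0.0025, adjusted p = 0.65 with an estimated correlation) and endodermis markers (0 of 8 called, median 0.96, adjusted p = 0.0014, adjusted p = 0.65 with an estimated correlation) were higher as sets; 1 gene of each was called adjusted over the list alone. The root marker mean, which averages these same genes in each library, was 3.43, 2.57 and 2.2 with ABA and 3.78, 3.26 and 3.75 with 3'-butyl ABA. Without ABA replicate 2 the RAB18 adjusted p of 0.011 became 0.057, and without 3'-butyl ABA replicates 1, 2 or 3 it became 0.058, 0.051 or 0.06; PYL6 moved from 0.01 to 0.058 without 3'-butyl ABA replicate 1, and NIA1 from 0.011 to 0.053 without ABA replicate 2 and 0.062 without 3'-butyl ABA replicate 1.

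Gene by gene, 160 genes were higher and 153 lower with 3'-butyl ABA than with ABA, 1.6% of those tested, with 42 and 13 at least 2-fold apart. With limma 3385 genes had an unadjusted p under 0.05, above the share of 0.05 that chance gives. The libraries did not overlap for 25.8% of the genes, where chance gives 10%. Chance gives these shares only on average, and genes that vary together can exceed them without an effect of the compound. The low number of calls does not show that few genes differ, and these shares do not show that many do. The 5 largest called increases by the rule for named genes were in AT2G38790 (2.37 ± 0.43, SE), AT5G54585 (1.82 ± 0.30), AT1G27020 (1.66 ± 0.25), the invertase/pectin methylesterase inhibitor superfamily gene AT4G25250 (1.60 ± 0.34) and the LEA-like gene AT5G60520 (1.57 ± 0.28). The 5 largest decreases were in AT1G62225 (-1.69 ± 0.37), RNS1, a ribonuclease gene (32.0 ± 4.48 to 10.4 ± 0.622 TPM; -1.53, interval -1.78 to -1.27), the aspartyl protease gene AT4G16563 (-1.45 ± 0.19), the transaminase gene CORI3 (-1.29 ± 0.24) and the oxygenase gene AT5G05600 (-1.27 ± 0.24). Without 3'-butyl ABA replicate 1, RNS1 alone of these 10 was called, the others having an adjusted p of 0.058 to 0.18. RNS1 stayed called without any 1 library. Another 8 genes, chosen after their values were seen because they did so too, were ZFP8 (-0.94), ASN2, an asparagine synthetase gene (-0.88), AT2G39400 (0.87), AT1G22190 (0.87), AT4G18205 (1.1), COL1 (0.74), AT5G19240 (0.88) and AT4G38550 (0.48). The count was not stable when 1 library was left out. It was 9, 71 and 55 without 3'-butyl ABA replicates 1, 2 and 3. Without ABA replicates 1, 2 and 3 it was 494, 50 and 111. A fit with 1 library fewer also has less power, and this was not told apart from the weight of single libraries. With the root marker mean of each library as a covariate 5 genes were called. The median absolute log2 fold change of the 313 genes went from 0.63 to 0.52, all in the same direction, and the median SE from 0.12 to 0.14.

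**Figure D3:**
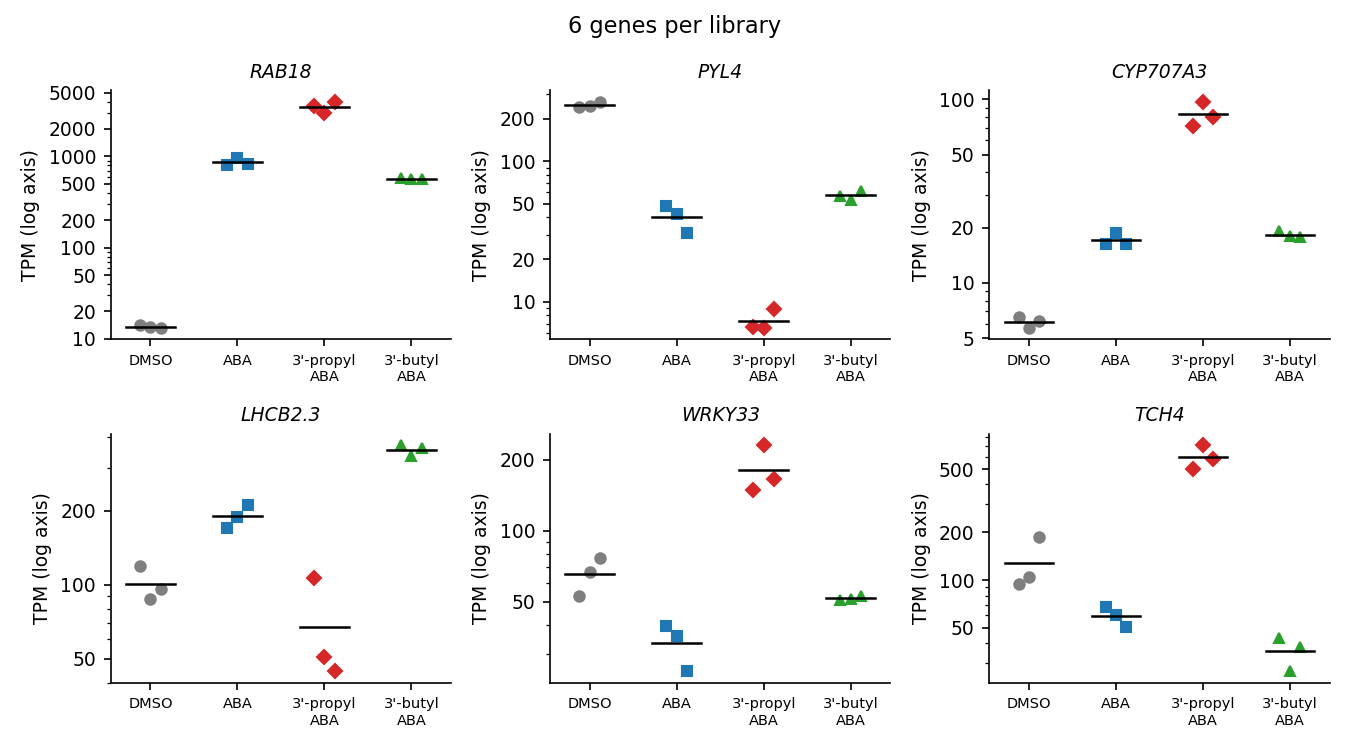
TPM of 6 genes in each of the 12 libraries on log axes; points are libraries and lines are group means (n = 3). RAB18 averaged 13.6, 863, 3512 and 567.5 TPM in DMSO, ABA, 3'-propyl and 3'-butyl ABA libraries, while WRKY33 and TCH4 were higher in every 3'-propyl ABA library than in any other.

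Between the derivatives, which differ by 1 carbon in the chain, 3'-butyl ABA gave higher light harvesting and receptor genes and lower dehydration genes than 3'-propyl ABA. All 20 light harvesting and Rubisco genes were higher (median 1.08, adjusted p = 2.7e-09, adjusted p = 0.41 with an estimated correlation), LHCB2.3 by 2.49 ± 0.27 (67.5 to 355 TPM) and RBCS1B by 2.34 ± 0.19. Of 20 LEA and dehydration genes 19 were lower and COR15B was not called (median -1.77, adjusted p = 7.4e-13, adjusted p = 0.35 with an estimated correlation). LTP4 was at -2.94 ± 0.14, RD20 at -2.81 ± 0.14 and RAB18 at -2.62 ± 0.09. PP2C genes were lower in 8 of 9 cases (median -0.71, adjusted p = 5.6e-06, adjusted p = 0.35 with an estimated correlation). HAI3 was at -1.49 ± 0.20 and ABI2 at -1.42 ± 0.10. Receptor genes were higher in 8 of 9 (median 1.11, adjusted p = 0.0013, adjusted p = 0.42 with an estimated correlation). PYL4 was at 2.82 ± 0.15 and PYL6 at 2.48 ± 0.22. CYP707A4 (-2.14), CYP707A3 (-2.11) and CYP707A2 (-1.79) were lower, in a catabolism list with 5 down and 1 up (median -0.84, adjusted p = 0.0015, adjusted p = 0.35 with an estimated correlation).

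Transcription factor (11 of 18 down, median -0.81, adjusted p = 1.9e-05, adjusted p = 0.4 with an estimated correlation), wax (5 of 8 down, 1 up, median -1.29, adjusted p = 0.00059, adjusted p = 0.35 with an estimated correlation), suberin (6 of 13 down, median -0.66, adjusted p = 0.00059, adjusted p = 0.43 with an estimated correlation), flavonoid (5 of 11 down, 1 up; 6 and 1 adjusted over the list alone; median -0.45, adjusted p = 0.0071, adjusted p = 0.43 with an estimated correlation) and jasmonate genes (7 of 20 down, 1 up; 5 and 1 adjusted over the list alone; median -0.39, adjusted p = 0.0064, adjusted p = 0.59 with an estimated correlation) were lower, with MYB2 at -2.26, CER1 at -2.06, KCS2 at -2.28 and PAP1 at -3.13. Ribosome biogenesis (13 of 14 up; 14 adjusted over the list alone; median 0.47, adjusted p = 0.00011, adjusted p = 0.41 with an estimated correlation), cell cycle (14 of 19 up; 16 adjusted over the list alone; median 0.43, adjusted p = 0.0018, adjusted p = 0.43 with an estimated correlation; 9 up with either other scaling) and auxin genes (11 of 16 up, 3 down; 11 and 4 adjusted over the list alone; median 0.77, adjusted p = 0.016, adjusted p = 0.41 with an estimated correlation) were higher, with FIB2 at 0.62, CYCD3;1 at 0.86 and IAA29 at 3.41. Endodermis markers gave 5 up of 8 (7 adjusted over the list alone; adjusted p = 0.079; called with median-of-ratios scaling, 0.019, and quantile normalization, 0.046), where the root marker mean was 3.26 to 3.78 with 3'-butyl ABA and 2.54 to 2.69 with 3'-propyl ABA. The largest differences were in GASA6, a gibberellin-regulated gene (3.92 ± 0.37), AT5G63180 (3.91 ± 0.16), EXPA8 (3.87 ± 0.17), AT1G15125 (3.87 ± 0.39) and AT3G23550 (3.81 ± 0.47), and in AT5G39520 (-4.79 ± 0.21), AMY1 (-4.30 ± 0.22), AT4G18422 (-4.28 ± 0.28), CSLG2 (-4.09 ± 0.29) and TCH4 (-4.03 ± 0.26). In total 6100 genes were higher and 3431 lower with 3'-butyl ABA, 48.8% of those tested, with 1132 and 861 at least 2-fold apart and no overlap of libraries for 61.9%. Of the called genes 64.0% were higher, 47.2% with median-of-ratios scaling, which moved the median of all genes from 0.131 to 0.013, and 52.7% with quantile normalization.

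**Figure D4:**
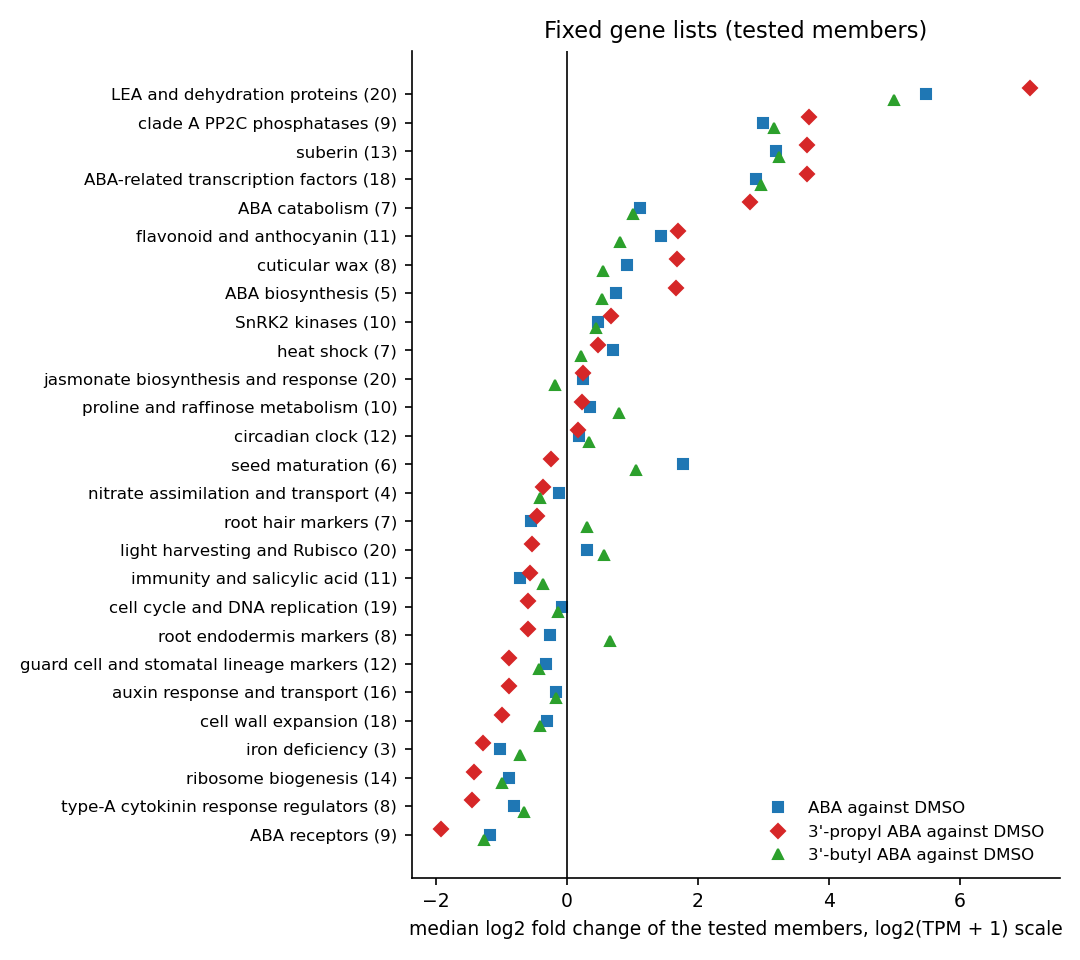
Median log2 fold change against DMSO of the tested members of 27 fixed gene lists for the 3 compounds, with the number of tested genes in brackets; each point is 1 list and compound. The LEA and dehydration list has medians of 5.48, 7.08 and 5, and the light harvesting list 0.30, -0.54 and 0.56.

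The genes called with the compounds overlapped. ABA and 3'-propyl ABA shared 3671 genes that rose and 4427 that fell, where independent lists of these sizes would share 1181 and 1856. Another 133 genes were called in opposite directions (88 to 125 without 1 of the DMSO libraries). ABA and 3'-butyl ABA shared 3682 and 4026 (1077 and 1232 for independent lists), with 1 opposite gene, BRG2 (0.31 with ABA, -0.34 with 3'-butyl ABA), whose call is lost without 1 library in both. This pair had 5 opposite genes with quantile normalization and 4 with both outlying libraries left out. The derivatives shared 3581 and 4265 (1347 and 1921), with 356 opposite genes (230 to 330 without 1 of the DMSO libraries, 236 with the root marker covariate). Across genes, which are not independent replicates, the fold changes had a Pearson r of 0.90, 0.94 and 0.83. All 3 comparisons use the same DMSO libraries. In 50 simulated draws without changed genes, a shared control group gave r = 0.50 and at most 1 shared gene. Covariances were 0.763, 0.561 and 0.711 against 0.014, 0.015 and 0.014 simulated. With no gene changed few shared calls could arise, and the simulated genes varied independently. The draws therefore cannot show how much of the shared counts comes from the controls. With only 3 DMSO libraries the controls could not be split, so part of the shared count can come from them.

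The genes called in opposite directions with ABA and 3'-propyl ABA included regulators of rapid stress responses. CAF1a, a deadenylase gene, went from 31.2 ± 9.09 TPM in DMSO to 9.47 ± 1.2 TPM with ABA and 80.6 ± 18.0 TPM with 3'-propyl ABA (-1.59 and 1.36, SE 0.20). SZF1 (-1.36 and 1.35), ERF6 (-1.45 and 1.31), DREB26 (-1.25 and 1.84) and the glycine-rich protein gene AT1G07135 (-1.48 and 1.08) followed. In all 53 genes fell with ABA and rose with 3'-propyl ABA, and 80 did the reverse. Against 3'-butyl ABA, 3'-propyl ABA had 209 genes down that rose with 3'-butyl ABA and 147 the other way, among them PHI-1 (1.85 with 3'-propyl ABA, -1.86 with 3'-butyl ABA) and TCH4 (2.25 and -1.77).

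As a single measure of response size, the mean log2(TPM + 1) of the 29 PP2C and LEA genes was taken per library. It was 3.43 ± 0.25 in DMSO, 8.28 ± 0.11 with ABA, 9.44 ± 0.12 with 3'-propyl ABA and 8.01 ± 0.12 with 3'-butyl ABA (SD, n = 3). The differences from DMSO were 4.85, 6.00 and 4.58. 3'-propyl ABA exceeded ABA by 1.15 (single pairs of libraries 0.91 to 1.34), and 3'-butyl ABA was below ABA by -0.27 (-0.51 to -0.08) and below 3'-propyl ABA by -1.42 (-1.65 to -1.19). Every library of 1 treatment lay on the same side of every library of the other in all 6 comparisons, and the two-sided exact permutation p was 0.1 in each, the smallest that 3 against 3 libraries allow.

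**Figure D5:**
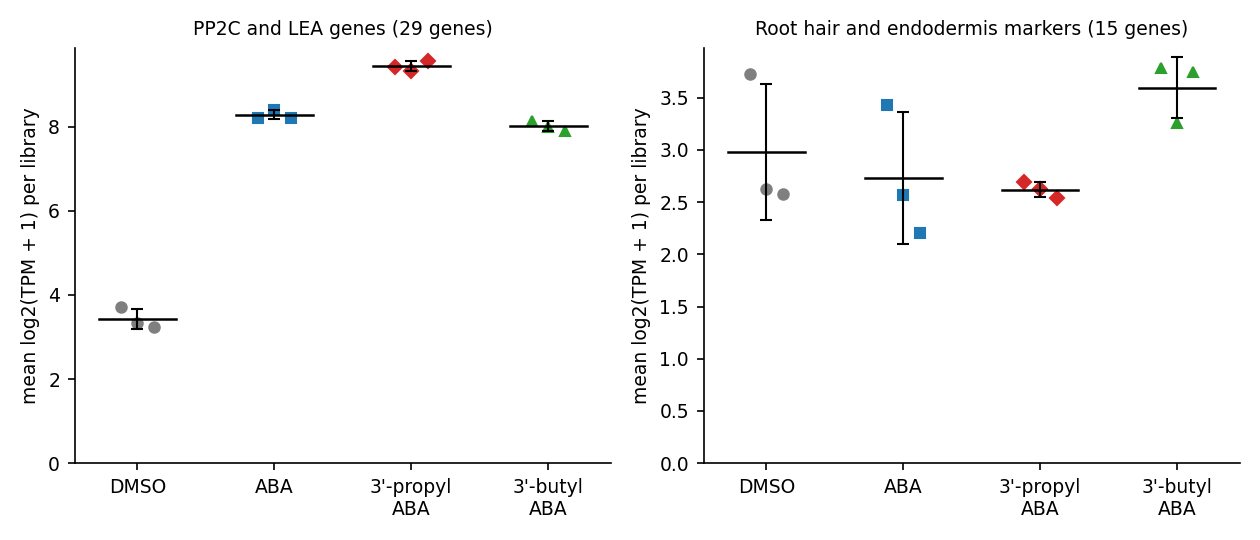
Mean log2(TPM + 1) per library of 29 PP2C and LEA genes (left) and of 15 root hair and endodermis markers (right); points are libraries, lines are group means and bars are 1 SD (n = 3). The left panel has means of 3.43 (DMSO), 8.28 (ABA), 9.44 (propyl) and 8.01 (butyl), and in the right panel DMSO and ABA libraries spread from 2.2 to 3.73.

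With genes chosen by a compound left out of the comparison, 3'-propyl ABA lay further from DMSO than the other compounds, while ABA and 3'-butyl ABA had no order. Among 1544 genes at least 2-fold higher with 3'-butyl ABA, the median log2 fold change over DMSO was 1.76 ± 0.10 with 3'-propyl ABA and 1.40 ± 0.16 with ABA (SD of 3 libraries), a difference of 0.37 (0.13 to 0.62), and 69.9% of the genes were higher with 3'-propyl ABA. Among 681 genes at least 2-fold lower with 3'-butyl ABA the medians were -1.67 ± 0.06 and -1.2 ± 0.06, a difference of -0.47 (-0.58 to -0.34). Among 2213 genes chosen with 3'-propyl ABA as higher, 3'-butyl ABA and ABA had medians of 1.07 ± 0.07 and 1.09 ± 0.14, a difference of -0.01 (-0.18 to 0.21), and among 2520 lower genes -0.72 ± 0.03 and -0.75 ± 0.06, a difference of 0.03 (-0.06 to 0.11). Among genes chosen with ABA, 3'-butyl ABA was below 3'-propyl ABA by -0.54 in the higher set and above by 0.71 in the lower set. Exact permutation p values were 1 and 0.6 for 3'-butyl ABA against ABA and 0.1, the smallest possible, for the others.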

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

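The root marker covariate, leaving out both outlying libraries, median-of-ratios scaling except for the 29-gene mean, quantile normalization except for counts of genes, every overlap setting except the fold change threshold, and leave-one-out for the 29-gene mean were chosen after the data were seen; the other settings were planned. No named gene or called list changed direction, but the majority direction of called genes and of shared genes is not stable. With median-of-ratios scaling that of shared genes turned for ABA and 3'-propyl ABA (4092 up, 4006 down), ABA and 3'-butyl ABA (3897, 3786) and the derivatives (4004, 3925). For ABA and 3'-butyl ABA it also turned without DMSO replicate 1 (3955, 3817). With median-of-ratios scaling that of called genes turned for ABA against DMSO (4616 up, 4511 down), 3'-propyl ABA against DMSO (6530, 6363), 3'-butyl ABA against DMSO (5046, 4894), 3'-propyl ABA against ABA (4140, 3533) and 3'-butyl ABA against 3'-propyl ABA (4264, 4762). For 3'-butyl ABA against ABA it turned with pseudocount 0.1 (105, 127). For ABA against DMSO it also turned without DMSO replicate 1 (4509, 4430), and near-even counts turned in some other settings too. The counts of called genes stayed within 1.5 times the reported ones for the comparisons other than 3'-butyl ABA against ABA under quantile normalization, no filter, only the 6 libraries compared, the replicate block, pseudocount 0.1, median-of-ratios scaling, the covariate and both outlying libraries (DMSO replicate 1 and ABA replicate 3) left out; the last gave 9191, 12806, 10435, 7922, 317 and 10553. For 3'-butyl ABA against ABA, 313 genes became 755 with the replicate block (replicate number as a factor; 7 of 12 libraries were closest to a library with their own number, and residual correlations were 0.12 to 0.33 for replicate 1 but -0.10 to 0.06 for replicate 3, a hint from the data and not the design), 5 with the root marker covariate, and 9 (without 3'-butyl ABA replicate 1) to 494 (without ABA replicate 1) in leave-one-out fits; the cause was tested for the covariate alone (see the closing part). Requiring an absolute log2 fold change of at least 1 gave 2038 (ABA against DMSO), 4733 (3'-propyl ABA against DMSO), 2225 (3'-butyl ABA against DMSO), 1249 (3'-propyl ABA against ABA), 55 (3'-butyl ABA against ABA) and 1993 (3'-butyl ABA against 3'-propyl ABA), and overlaps of 1841, 1579 and 1758, since fewer genes can pass. Leave-one-out counts ranged from 7517 to 8939, 11979 to 12468, 8308 to 9969, 6540 to 7590 and 7824 to 8877 for the other comparisons in this order. Leave-one-out overlaps were 7044 to 7873 (ABA and 3'-propyl ABA), 6536 to 7772 (ABA and 3'-butyl ABA) and 6893 to 7814 (3'-propyl ABA and 3'-butyl ABA). With the replicate block 151, 15 and 418 genes of these pairs were called in opposite directions. The 29-gene mean differed from DMSO by 4.76 to 4.99 (ABA), 5.91 to 6.14 (3'-propyl ABA) and 4.49 to 4.72 (3'-butyl ABA) in leave-one-out, by 1.09 to 1.21 for 3'-propyl ABA against ABA, -0.33 to -0.21 for 3'-butyl ABA against ABA and -1.49 to -1.36 for 3'-butyl ABA against 3'-propyl ABA; pseudocount 0.1, which weighs low values more, gave 5.33, 6.49 and 5.06 against DMSO, and median-of-ratios scaling gave -1.55 for 3'-butyl ABA against 3'-propyl ABA (cause not tested). Of 162 list tests 81 were called, 0 with an estimated correlation (smallest adjusted p 0.078), 85 with the replicate block (endodermis markers at 0.014 between the derivatives and 0.036 for 3'-butyl ABA against DMSO, seed maturation at 0.048 for ABA against DMSO, nitrate at 0.045 for 3'-propyl ABA against ABA), 83 with median-of-ratios scaling and 84 with quantile normalization, with 0 opposite directions. For named genes over all settings, 10020 results kept direction and side of the threshold, 489 lost the call, 99 gained it and 0 reversed. The planned count-based Wald test (DESeq2), the count filter and the second count scaling were not run, because the values are not counts. At an estimated 9.64 to 12.4 times 1000000 reads per library, a gene of 1 kb at 1 TPM rests on fewer than 10 reads. Changes of 0.5 log2 units were mostly missed in simulated data (14.9% recovered), whose spread and number of changed genes were not those of these libraries.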

Other observations

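The families and the low-oxygen and touch lists below, and the tests of scaling, of ABA replicate 3 (lower set) and of response sizes with the covariate for the first pattern, of folds and errors with the covariate for the second and of touch for the third, were chosen after the data were seen. Among 117 annotation families with at least 15 tested genes, the ones named here were picked for their changes. Of 179 genes of the pentatricopeptide repeat (PPR) superfamily, whose members process chloroplast and mitochondrial RNA, 90 fell with ABA, 143 with 3'-propyl ABA and 111 with 3'-butyl ABA, while 1, 2 and 1 rose (medians -0.36, -0.79 and -0.45, adjusted p = 7.4e-07, 2.4e-09 and 1.2e-09, adjusted p = 0.49, 0.42 and 0.43 with an estimated correlation). Between 3'-propyl ABA and ABA 100 of them were lower and 0 higher (median -0.43; 77 and 3 with median-of-ratios scaling, 43 and 0 with quantile normalization, median -0.26), and between 3'-butyl ABA and ABA 0 were called with limma. Of 18 DEA(D/H)-box RNA helicase genes 16, 17 and 15 fell with the 3 compounds (adjusted p = 3.9e-06, 2.3e-05 and 2.4e-06, adjusted p = 0.49, 0.46 and 0.43 with an estimated correlation), and of 22 small nuclear ribonucleoprotein genes 17, 19 and 17 fell (adjusted p = 0.00011, 0.00067 and 0.00018, adjusted p = 0.23, 0.42 and 0.29 with an estimated correlation). Of 56 SAUR-like auxin-responsive genes 41 fell and 9 rose with 3'-propyl ABA (median -1.33, adjusted p = 0.0016, adjusted p = 0.46 with an estimated correlation). Of 154 alpha/beta-hydrolase genes 66 rose and 19 fell with ABA, 81 and 27 with 3'-propyl ABA, and 69 and 17 with 3'-butyl ABA (adjusted p = 0.00034, 0.00014 and 0.00018, adjusted p = 0.7, 0.55 and 0.59 with an estimated correlation). No family was called with an estimated correlation (smallest adjusted p = 0.23), and these directions held with both other scalings.

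Of 20 rapid touch and wound genes, 12 fell and 1 rose with ABA, 14 rose and 1 fell with 3'-propyl ABA, and 8 fell and 1 rose with 3'-butyl ABA; between 3'-propyl ABA and ABA 16 were higher and 0 lower (median 2.12, adjusted p = 4e-12, adjusted p = 0.57 with an estimated correlation). ERF5 rose by 2.18 ± 0.21 and ZAT10 (STZ) by 2.14 ± 0.25 with 3'-propyl ABA against DMSO (SE, n = 3). Of 20 low-oxygen genes 2 rose and 1 fell with ABA, 2 and 2 with 3'-propyl ABA, and 8 and 1 with 3'-butyl ABA, the last with ADH1 at 1.98 ± 0.59; between 3'-butyl ABA and ABA 0 were called (median 0.84, adjusted p = 0.0028, adjusted p = 0.88 with an estimated correlation). ADH1 was at 1110, 812 and 238 TPM in the 3 ABA libraries and at 1350, 813 and 880 TPM in the 3'-butyl ABA libraries.

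The first pattern is the larger distance from DMSO with 3'-propyl ABA than with ABA. Scaling to a fixed total would move all genes 1 way, but the median difference was -0.47 in the lower set beside 0.37 in the higher set, with no overlap of libraries. ABA replicate 3 alone is argued against for the lower set, where the difference without it stayed at -0.47, while in the higher set it fell from 0.37 to 0.27, between the bounds set for either reading, so that part stays open. For a different share of root tissue, the root marker mean differed by only -0.11. The 3'-propyl ABA libraries (2.54 to 2.69) lay within the range of the ABA libraries (2.2 to 3.43), so these markers show no clear difference in root share. With the root marker covariate the median differences were 0.4 (0.1 to 0.59 for single pairs of libraries) and -0.48 (-0.6 to -0.36). The count of called genes was 8799 with the covariate and 8169 without. With so small a marker difference the medians and the count had little room to move, so the covariate fit cannot decide on root tissue. A stronger response to 3'-propyl ABA at the same dose is the biological hypothesis that the design offers; uptake and stability of the compounds were not measured.

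The second pattern is the set of 313 genes called between 3'-butyl ABA and ABA. The share of root tissue may account for part of it: 80.8% moved between the treatments as they followed the root marker mean within treatments (68.6% of all genes), just past the bound of 80%, and oxygen around the seedlings could serve as well, with 80.5% (68.1% of all genes) for the low-oxygen mean. The median share of the observed change predicted from the variation within treatments was 0.16 for the root marker mean and 0.12 for the low-oxygen mean. Genes that vary little within treatments are called more easily, and their predicted changes tend to be small too. These shares therefore cannot show how much either mean accounts for. The group differences of 0.86 and 0.83 in these means had exact permutation p values of 0.2 and 0.3. The root marker covariate left 5 calls. The median absolute log2 fold change of the 313 genes went from 0.63 to 0.52, with all in the same direction, and the median SE from 0.12 to 0.14. Of the 313, 123 stayed called with only the folds of that fit, 124 with only its errors and 294 with only its degrees of freedom. Smaller folds and larger errors each ended many calls, so the number of lost calls cannot decide on root tissue. The compound itself stays open as the biological explanation, and was not tested apart from these.

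The third pattern is the 53 genes lower with ABA and higher with 3'-propyl ABA. With median-of-ratios scaling 46 of 53 were called in both directions. That scaling moved the median of all genes from -0.116 to 0.005 with 3'-propyl ABA and from -0.029 to -0.007 with ABA. It therefore favoured a rise with 3'-propyl ABA and hardly touched a fall with ABA, so this count cannot decide on scaling. Touch or wounding at harvest was left undecided: 14 of 20 touch and wound genes rose with 3'-propyl ABA, but 10 of the 20 are in the pattern, so this count partly restates it. Outside the pattern 4 of 10 rose and TCH3 alone fell (-1.75 ± 0.24), under the bound of 50%, but leaving out genes that rose lowers this count by design. The order of harvest is not in the labels, so handling and compound cannot be told apart.

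Each comparison was also recounted over all 10 splits of its 6 libraries into 3 and 3. Only the real split, 1 of 10, gave as many genes: 9116 against at most 4 in another split for ABA and DMSO, 12889 against 0 for 3'-propyl ABA and DMSO, 9890 against 0 for 3'-butyl ABA and DMSO, 8169 against 2 for 3'-propyl ABA and ABA, 313 against 0 for 3'-butyl ABA and ABA, and 9531 against 0 for 3'-butyl ABA and 3'-propyl ABA. Every other split mixes both treatments in each group, which adds their difference to the spread, so counts there are low by design. With 10 splits the share cannot go under 0.1. No conclusion is drawn from these counts.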
